A study of Homo sapiens with 5 samples.

How the data were processed

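RNA levels were measured in H157, a human non-small cell lung carcinoma cell line, after small interfering RNA (siRNA) was used to lower DJ-1, the product of the gene PARK7. Per the labels, cells in RPMI medium with 10% fetal calf serum were transfected on 3 consecutive days, 24 hours apart, and lysed 96 hours after the first transfection. Total RNA was purified on columns with DNase treatment, biotin-labelled cRNA was made from it, and each sample was hybridised to 1 Affymetrix U133A array, which measures each transcript with 1 or more probe sets. Of the 5 arrays, 1 came from cells given transfection reagent alone (siMOCK), 2 from cells given a scrambled siRNA (siCTL) and 2 from cells given siRNA against DJ-1 (siDJ1). The labels do not say whether arrays of a group came from separate cultures or, for siDJ1, from separate oligonucleotides, so the p-values measure only the spread between these arrays, which may be technical.

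The deposited values are intensity values on a linear scale, 1 signal per probe set and array for 22283 probe sets. Per the submitters' processing notes the authors used MAS5, Affymetrix's summary of perfect-match and mismatch probes; its version, background settings and detection calls are not given in the sources used here. Each deposited column already had a 2% trimmed mean between 500.16 and 500.204, so the authors' scaling had set a common level, and differences in total RNA content between samples cannot be read from the values. MAS5 leaves large relative errors at low signal. Array data have no read depth, and the number of arrays limits the precision.

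Each array was rescaled to the common 2% trimmed mean of 500.185, and values were analysed as log2(signal + 25.0), where the pseudocount is 5% of the trimmed mean. Log2 changes of dim probe sets are understated by this pseudocount. After 68 array control probe sets were left out, probe sets with a mean log2 signal at or above the 40th percentile were kept, which corresponds to a signal of about 100.1 and left 13329 probe sets. Gene symbols came from the platform annotation supplied with the data, in which 19065 probe sets have 1 symbol, 1043 have several and 2107 are unnamed here. Of those with 1 symbol, 19053 were matched by gene ID to the RefSeq gene table of assembly GRCh38.p14, and 0 symbols differed. No gene was named from a probe set with several symbols. One gene fixed in advance as a named gene is not reported here.

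Tests used limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to all 5 arrays, with 2 residual degrees of freedom from the siCTL and siDJ1 arrays, an intensity trend in eBayes and Benjamini-Hochberg adjustment over the kept probe sets at a threshold of 0.05. The single mock array was assumed to vary like the replicated groups. For gene lists, 1 probe set per gene was used, that with the highest mean signal, which gave 8209 genes. Of 29 lists, 27 had at least 5 measured genes and were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over lists; camera with an estimated correlation and fry were alternatives. The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined.

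That rule named all PARK7 probe sets and, in each direction, the 12 genes with the largest gap between the nearest siDJ1 array and the nearest of the 3 control arrays, judged on the probe set with the highest mean signal of each gene. It also named up to 3 members of each list by the size of the moderated statistic, a fixed set of antioxidant genes, and, in each direction, the 5 genes with the largest gap of both siCTL arrays from the mock array, judged on the same probe sets. Probe sets separating a choice of arrays from all others by at least 1.5-fold were counted for every choice of 1 or 2 arrays.

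The ribosomal RNA control probe sets of the array were used to look for differences between arrays outside the groups. They divided the arrays into a low pair, siMOCK and siDJ1 array 1, and a high trio, both siCTL arrays and siDJ1 array 2. After the data were examined, a second model was therefore added with this array split as a block and siMOCK and siCTL as 1 control group, again with 2 residual degrees of freedom. In it the siDJ1 effect is estimated inside the low pair and inside the high trio. Inside the low pair the only control is siMOCK, so any effect of receiving siRNA is part of that estimate. The difference between siCTL and siMOCK cannot be separated from the split.

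The procedure was tested on simulated arrays with the real means and spreads for all 13329 probe sets. With the spread of the group model for siDJ1 against siCTL, 0 of 67 simulated 1.5-fold changes, 10 of 67 at 2-fold and 65 of 66 at 4-fold were recovered, with 14 false calls among 89. With the array split as a block, for siDJ1 against controls, 13 of 67, 50 of 67 and 66 of 66 were recovered, with 17 false calls among 146. Both shares of false calls, 15.7% and 11.6%, were above the nominal 5% in these single simulations. Simulated probe sets varied independently and the split was set in advance, so the shares in the real data may differ. In a simulated lowering of the G2/M list by 0.5 log2 units in siDJ1 against siCTL, that list passed and 0 of the other lists did. Without correlated genes, this cannot show how correlation within a list affects the list test. Other settings tried were the pseudocount, quantile normalisation, no rescaling, the filter, the variance trend, the replicate number as a block, pooled controls, another probe set per gene, and leaving out each replicated array in turn. A block for slide or scan date was not run, since neither is given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.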

Results

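The series asked how transcript levels in H157 lung carcinoma cells differ when DJ-1 is knocked down. DJ-1 is a small redox-sensitive protein encoded by PARK7, whose loss causes an inherited form of Parkinson disease, and it has been studied as a factor acting on NRF2, the transcription factor of antioxidant genes. The data comprise 5 arrays: 1 with reagent alone (siMOCK), 2 with scrambled siRNA (siCTL) and 2 with siRNA against DJ-1 (siDJ1). Signals are MAS5 values with a 2% trimmed mean of about 500 on each array, median signals lay between 147.7 and 170.7, and the 13329 brighter probe sets were tested.

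The arrays differed in a way the groups do not account for. Ribosomal RNA control probe sets had a geometric mean signal of 70.9 on the siMOCK array and 27.4 on siDJ1 array 1, against 432.1, 1090 and 389.1 on siCTL array 1, siCTL array 2 and siDJ1 array 2. The first principal component, with 57.7% of the variance, divided the arrays in the same way, and the second, with 24.2%, placed both siDJ1 arrays opposite the 3 controls. Across kept probe sets, which are not independent replicates, the log2 signals correlated at r = 0.981 between the 2 siCTL arrays, 0.939 between siMOCK and siDJ1 array 1, and 0.933 between the 2 siDJ1 arrays. The ratio of 3' to 5' signal for ACTB was 1.89 on siMOCK and between 1.02 and 1.28 on the other arrays. The spiked hybridisation controls stood at 61.2% of the siCTL mean on siDJ1 array 1 and at 130.6% on siDJ1 array 2. Because of this structure PARK7, the probe set counts, the lists that passed and the NRF2 targets are given also with the array split as a block, a model added after the data were examined, or as the change of siDJ1 array 1 from siMOCK and of siDJ1 array 2 from the siCTL mean. The siMOCK cells received no siRNA, so the change of siDJ1 array 1 from siMOCK also holds any effect of siRNA itself.

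**Figure D1:**
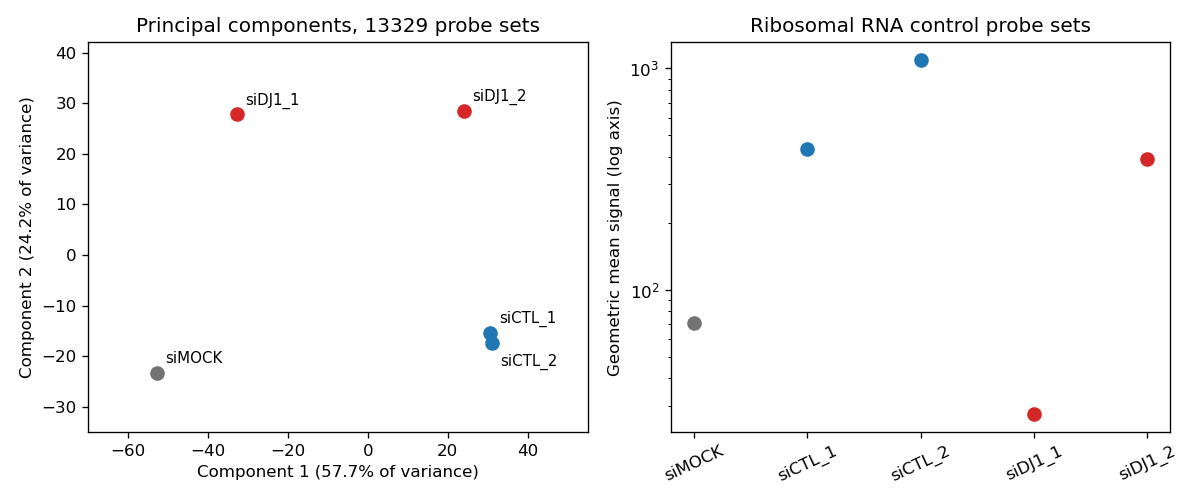
Left, scores of the 5 arrays on the first and second principal components of the log2 signals, with the percentage of variance on each axis. Right, geometric mean signal of 9 ribosomal RNA control probe sets per array on a log axis; siMOCK (70.9) and siDJ1 array 1 (27.4) lie below the other 3 arrays.

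The targeted gene was examined first. The PARK7 probe set (200006_at) had a signal of 12046 on siMOCK, 14433 ± 1321 (SD, n = 2) in siCTL and 3942 ± 1098 (SD, n = 2) in siDJ1, so both arrays labelled siDJ1 were lower than all 3 controls. The log2 difference between siDJ1 and siCTL was -1.89 (SE 0.27), a 3.71-fold lower signal, with a limma adjusted p of 0.116. With the array split as a block, PARK7 fell by 1.74 log2 units (SE 0.15, limma adjusted p = 0.00475), and the separate changes were -1.92 for siDJ1 array 1 and -1.60 for siDJ1 array 2.

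Knock-down of DJ-1 was next compared with the scrambled siRNA over all genes, ranked by 1 probe set per gene, that with the highest mean signal. On these probe sets the genes lying farthest below all controls in both siDJ1 arrays were PSMB8, an interferon-inducible proteasome subunit, CLNS1A, a chaperone of splicing-particle assembly, TMED2, a cargo receptor of vesicles between endoplasmic reticulum and Golgi, the mitochondrial isocitrate dehydrogenase IDH2, AMMECR1, PARK7 itself, LEPROT, SHCBP1, the Golgi protein TMF1, the RNA polymerase I factor RRN3, the chromatin protein PSIP1 and the lysosomal membrane protein LAMP1. TMED2 (200087_s_at) stood at 6932 ± 364.1 in siCTL and 1494 ± 146.0 in siDJ1 (SD, n = 2 each), a 4.59-fold difference, and CLNS1A at 2498 ± 37.8 and 661.2 ± 54.0. On the same probe sets the genes farthest above all controls were SERPINB7, a serine protease inhibitor, IGKC, TFPI2, an extracellular inhibitor of coagulation proteases, CCN2 (connective tissue growth factor), the elongation factor ELL2, the vesicle-fusion protein YKT6, the lysosomal sialidase NEU1, CPM, the small GTPase GEM, PDP1, the iron reductase CYBRD1 and RNF11. TFPI2 was at 3594 ± 431.4 in siCTL and 9469 ± 229.2 in siDJ1, a 2.63-fold difference, and CCN2 at 549.8 ± 56.4 and 1854 ± 371.4, a 3.24-fold difference. The differences spanned 2.55-fold to 7.01-fold for the 12 lower genes and 1.92-fold to 4.25-fold for the 12 higher genes.

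None of these genes passed the limma test of siDJ1 against siCTL, in which adjusted p ranged from 0.0930 to 0.140 for the lower and from 0.116 to 0.209 for the higher genes. In that test 0 of 13329 probe sets passed, the smallest adjusted p was 0.0685, and 1904 had an unadjusted p under 0.05, 979 of them higher and 925 lower in siDJ1. With the array split as a block, 268 probe sets passed, of which 86 rose (74 named genes) and 182 fell (153 named genes). In a simulation of this model 11.6% of calls were false, above the nominal 5%. That share is not an error rate of the 268, since simulated probe sets varied independently and the split was set in advance. All 12 lower genes and 11 of the 12 higher genes were among the 268 calls, and CPM had a limma adjusted p of 0.0538. This is no separate support, since these genes were chosen by their gap from the controls on the same arrays. Leaving out either siDJ1 array raised the count of the group model, where the spread rests on the 2 siCTL arrays alone. The rise was far larger without siDJ1 array 2, where the siDJ1 array left lies across the split from siCTL. A count without a variance model found 239 probe sets with both siDJ1 arrays beyond all 3 controls by at least 1.5-fold, 73 higher and 166 lower. Any gap at all in either direction was found for 22.8% of probe sets, close to the 20% given by a random order of the arrays. The 5 other choices of 1 array from each side of the split gave 10 to 29 probe sets at 1.5-fold and any gap for 8.1% to 14.4%. Choices of 2 arrays from the same side gave 37 to 1309 probe sets and any gap for 18.3% to 46.7%. Among them the siCTL pair gave 369 and 33.5%, more than the siDJ1 pair.

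Several of these genes had more than 1 kept probe set. The 3 probe sets of TMED2 were all lower in siDJ1, at -2.74 to -2.20, although on siDJ1 array 1 the 2 dimmer ones, 204426_at and 204427_s_at, lay at -0.02 and -0.23 from siMOCK. LAMP1 was lower on 2 of 3 probe sets and the remaining one was at 0.34. PSIP1, IDH2 and TMF1 each had a probe set with a much smaller difference, at -0.02, -0.03 and -0.30. The IGKC probe set is of a type whose probes can bind several transcripts, and its other probe set was at 0.30.

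**Figure D2:**
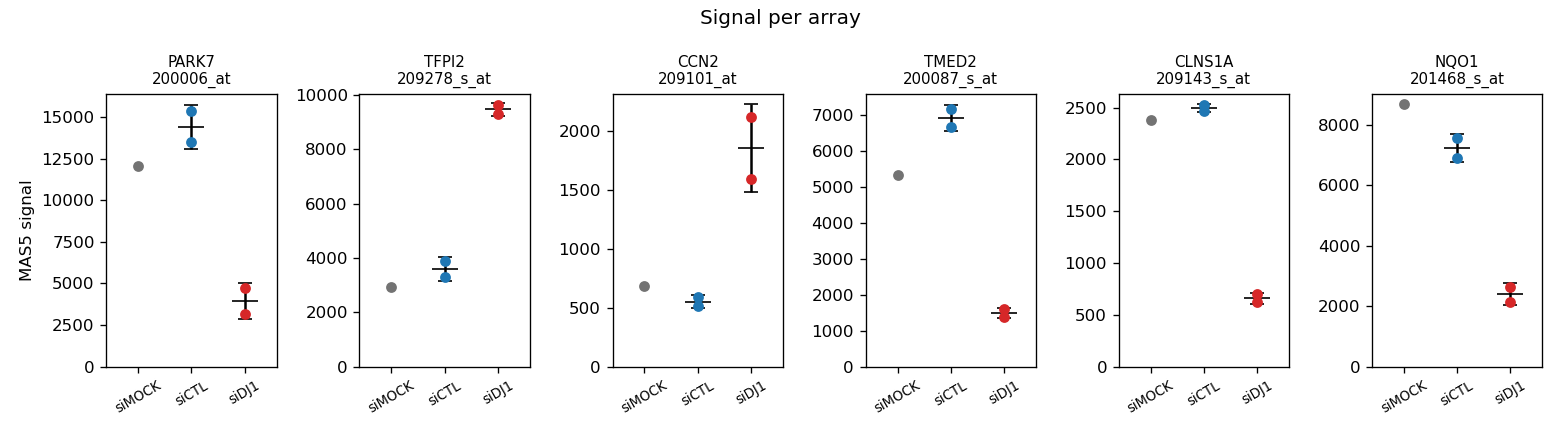
MAS5 signal (linear axis from 0) of 6 genes per array, points being arrays and bars the mean ± SD of the 2 siCTL and the 2 siDJ1 arrays. Both siDJ1 arrays lie below all controls for PARK7, TMED2, CLNS1A and NQO1 (201468_s_at) and above them for TFPI2 and CCN2. For NQO1 the probe set shown is the one with the largest difference between siDJ1 and siCTL, not the brightest.

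Genes of cell division were lower in siDJ1. The G2/M list fell by 0.45 log2 units on average against siCTL (camera, preset correlation, adjusted p = 1.53e-05; adjusted p = 0.980 with an estimated correlation), and 27 of its 30 genes had a negative difference. Those with the largest statistics were CENPE, a kinesin of the kinetochore (-1.07), CCNB1, cyclin B1 (-0.84), and the kinesin KIF2C (-0.69). The DNA replication list fell by 0.37 on average (adjusted p = 0.000131; adjusted p = 0.980 with an estimated correlation), with 23 of 29 genes negative, among them RFC3 (-1.04) and RFC5 (-1.17) of the clamp loader and the helicase subunit MCM6 (-0.93); RFC5 was at 0.42 in siDJ1 array 1 against siMOCK, and its other 2 kept probe sets were at -0.50 and -0.23. The other kept probe set of RFC3, 204128_s_at, was at -0.87 against siCTL, but at 0.55 in siDJ1 array 1 against siMOCK. Single genes of both lists did not pass in this comparison, whether adjusted over all probe sets or, as 0 of 30 and 0 of 29, adjusted over the list alone. With an estimated correlation no list passed. That test rests on the 2 residual degrees of freedom and has little power here. For the replication list the estimate was -0.014, below the preset 0.01, yet the unadjusted camera p rose from 9.7e-06 to 0.0377. For endoplasmic reticulum chaperones the estimate was -0.021. The estimate was above the preset for the G2/M list (0.18), interferon-stimulated genes (0.11), inflammatory genes (0.16) and complexes II to V (0.48). If genes of these last lists are that correlated, their p-values at the preset are too small. With the array split as a block the G2/M list fell by 0.41 and the replication list by 0.42 (camera; adjusted p = 0.655 for both with an estimated correlation), and 6 and 14 members fell, while 1 replication gene rose, when adjusted over the list alone. Adjusted over all probe sets, 2 members of each list fell, the mitotic regulators AURKA and CDC20 and the nucleotide and DNA repair enzymes RRM2 and UNG, which are named here after their values were seen. The mean G2/M change was -0.58 for siDJ1 array 1 from siMOCK and -0.28 for siDJ1 array 2 from siCTL, and that of the replication list -0.46 and -0.39.

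Interferon-stimulated genes fell by 0.39 log2 units on average against siCTL (camera, adjusted p = 0.00276; adjusted p = 0.980 with an estimated correlation), with 21 of 30 genes negative. The immunoproteasome subunits PSMB8 (-2.81) and PSMB9 (-1.40) and IFIT5 (-1.07) had the largest statistics, and 4 members were lower when adjusted over the list alone, against 0 over all probe sets. PSMB8 and PSMB9 fell with the array split as a block, at -2.37 and -1.29. NF-kB and inflammatory genes fell by 0.47 on average (camera, adjusted p = 0.0102; adjusted p = 0.980 with an estimated correlation), with 16 of 21 genes negative and 1 lower when adjusted over the list alone. CXCL2, a neutrophil chemokine, was at -1.20, CCL20, a lymphocyte chemokine, at -3.34 and the pentraxin PTX3 at -1.13. CCL20 was at 0.14 in siDJ1 array 1 against siMOCK, but on both arrays its signal lay below the filter cutoff, so a fall could hardly show. Both lists were uneven over the array split, with mean changes of -0.13 and -0.03 for siDJ1 array 1 from siMOCK and of -0.47 and -0.70 for siDJ1 array 2 from siCTL. Without siDJ1 array 2 the interferon and inflammatory lists no longer passed (camera, adjusted p = 0.157 and 0.456).

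Endoplasmic reticulum chaperones rose by 0.38 log2 units on average against siCTL (camera, adjusted p = 0.0106; adjusted p = 0.980 with an estimated correlation), with 17 of 20 genes positive and 2 higher when adjusted over the list alone. The protein disulphide isomerase PDIA6 was at 1.03 and lay at 4106 ± 66.0 in siCTL and 8393 ± 185.3 in siDJ1 (SD, n = 2 each), and the secretory-pathway proteins CRELD2 and SDF2L1 were at 0.95 and 0.91. HSPA5, the main chaperone of the compartment, was at -0.67; it is named here after its value was seen. Without siCTL array 1 the list had an adjusted p of 0.0583. The list's mean change was 0.42 for siDJ1 array 1 from siMOCK and 0.30 for siDJ1 array 2 from siCTL. With the array split as a block the list rose by 0.35 (camera; adjusted p = 0.655 with an estimated correlation), and PDIA6 and MANF rose by 0.86 and 0.82. Subunits of mitochondrial complexes II to V fell by 0.20 on average (camera, adjusted p = 0.0491; adjusted p = 0.980 with an estimated correlation), with 27 of 35 genes negative; their change was -0.25 on siDJ1 array 1 from siMOCK and 0.02 on siDJ1 array 2 from siCTL. UQCR11, a small subunit of complex III, fell by 1.38 with the array split as a block, a model in which the list did not pass. Without siCTL array 1, siCTL array 2 or siDJ1 array 1 the list did not pass either (adjusted p = 0.267, 0.106 and 0.275).

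**Figure D3:**
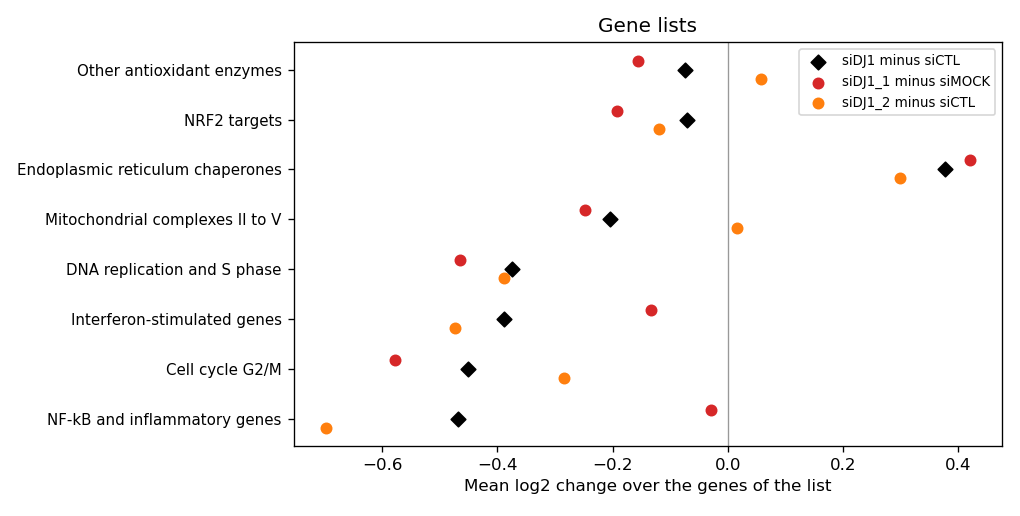
Mean log2 change over the genes of the 6 lists that passed camera for siDJ1 against siCTL and of the NRF2 target and antioxidant enzyme lists. Diamonds are siDJ1 minus siCTL and circles the separate changes of each siDJ1 array; the circles lie on the same side of 0 for the cell cycle, replication, interferon, inflammatory, chaperone and NRF2 target lists.

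The question of antioxidant genes was examined with the list of NRF2 targets. Its 31 measured genes had a mean change of -0.07 log2 units between siDJ1 and siCTL, 17 being negative, and the list did not pass (camera, adjusted p = 0.537). Over 16 settings with camera at the preset correlation it passed in 0, with means from -0.17, with the probe set of largest variance per gene, to -0.02, without siDJ1 array 2. None of its genes passed over all probe sets, and 2 were lower when adjusted over the list alone. Individual targets differed among themselves. NQO1, the quinone reductase often used as the readout of NRF2, was lower on all 3 of its probe sets, at -1.59 (201468_s_at), -0.82 (201467_s_at) and -0.68 (210519_s_at); the first went from 7247 ± 469.0 in siCTL to 2395 ± 361.3 in siDJ1 (SD, n = 2 each) and the brightest from 12519 ± 1466 to 7868 ± 1889. The drug transporter ABCC3 was at -1.60, the iron-binding protein PIR at -0.71, and GCLM, the modifier subunit of glutathione synthesis, at -0.65. HMOX1, haem oxygenase 1, was at 0.70, TXNRD1, thioredoxin reductase, at -0.38, and the catalytic subunit GCLC at -0.02 and -0.03 on its 2 probe sets. SLC7A11, the cystine transporter, was at -0.99 on 2 probe sets and at 0.70 on the third. NFE2L2, which encodes NRF2, was at -0.25, and its inhibitor KEAP1 at 0.29, which turned to -0.07 with the array split as a block. None of these passed in the test against siCTL. With the split as a block the list was at -0.15 (camera, adjusted p = 0.372). In that model ABCC3 fell by 1.82 (limma adjusted p = 0.00819) and NQO1 fell by 1.68 on 201468_s_at (limma adjusted p = 0.00719). The other NQO1 probe sets had limma adjusted p-values of 0.0564 and 0.0889. SLC7A11 fell by 0.85 and 1.08 on 2 of its 3 probe sets, 209921_at and 217678_at.

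The other 21 lists did not pass for siDJ1 against siCTL, with mean changes between -0.18 and 0.26 and adjusted p between 0.108 and 0.998. Among them, NRF2 pathway regulators had a mean change of 0.25, with 2 genes higher when adjusted over the list alone, other antioxidant enzymes -0.07, the PI3K pathway list 0.14, p53 targets -0.09, FOXO targets 0.08, apoptosis regulators 0.08, Parkinson disease genes including PARK7 -0.07, and heat shock genes 0.08. Genes of hypoxia and glycolysis were at 0.08, ATF4 and amino acid response 0.26, extracellular matrix 0.19, cholesterol synthesis -0.00498, fatty acid synthesis -0.05, proteasome subunits -0.18, complex I -0.10, cytosolic ribosomal proteins -0.17 and small RNA machinery -0.05. Several of these means moved with the setting. Over the same 16 settings ATF4 genes ranged from -0.03, with the array split as a block, to 0.48, fatty acid synthesis from -0.39, with that block, to 0.27, proteasome subunits from -0.46 to 0.09, complex I from -0.37 to 0.18 and ribosomal proteins from -0.47 to 0.13. Complex I and ribosomal proteins passed camera as higher without siDJ1 array 1 and as lower without siDJ1 array 2. ATF4 genes passed in 2 settings and proteasome subunits in 1. For autophagy and lysosome genes the mean was 0.22, and this list rose by 0.17 with the array split as a block (camera, adjusted p = 0.0281; adjusted p = 0.655 with an estimated correlation), with NEU1 rising and LAMP1 falling. In 4 of these 21 lists the mean, the median and the test did not share a sign. Markers of lung epithelium and of fibroblasts and endothelium had means of 0.01 and -0.04. Markers of immune and neuroendocrine cells left 2 and 4 measured genes and were not tested; T-cell CD3E stood at 201.1 ± 56.9 in siCTL and 240.1 ± 36.4 in siDJ1.

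Against the reagent-only control, the same siDJ1 arrays also had lower cell division lists, so this is not a separate observation. The G2/M list fell by 0.41 and the replication list by 0.48 log2 units (camera, adjusted p = 0.00911 and 0.00537), and endoplasmic reticulum chaperones rose by 0.34 (adjusted p = 0.0167); with an estimated correlation each had an adjusted p of 0.920. NRF2 targets were at -0.24 (adjusted p = 0.491). In limma 0 probe sets passed, with a smallest adjusted p of 0.103 and 2023 at an unadjusted p under 0.05. Of the lists that passed against siCTL, interferon-stimulated genes (-0.22), inflammatory genes (-0.26) and complexes II to V (-0.03) did not pass here. The comparison rests on 1 mock array, which sits with siDJ1 array 1 on the ribosomal RNA controls. Leaving out a siCTL or a siDJ1 array raised the count of called probe sets. The rise was largest without siDJ1 array 1, where the siDJ1 array left lies across the split from siMOCK.

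The scrambled siRNA was compared with reagent alone as the measure of what siRNA transfection does without the DJ-1 target. Ranked by the same 1 probe set per gene, the genes with the largest gap above the mock array in both siCTL arrays were the chemokine CCL20 (34.6 on siMOCK, 1673 ± 662.8 in siCTL, SD, n = 2), TAF9B, the ubiquitin ligase HUWE1 (1824 and 18311 ± 1113 on 207783_x_at, but 3061 and 1251 ± 69.8 on its other kept probe set, 208598_s_at), complement C3 (45.8 and 539.7 ± 26.4) and MAGOHB. Those farthest below were TKT, transketolase (8461 and 534.2 ± 12.8), APBA2, MYL9, MAPK3 and GANAB. In limma 0 probe sets passed, the smallest adjusted p being 0.0724, and 2985 had an unadjusted p under 0.05, 1446 higher and 1539 lower in siCTL. Of the lists, ATF4 and amino acid response genes fell in siCTL, by 0.60 log2 units on average (camera, adjusted p = 0.0274; adjusted p = 0.919 with an estimated correlation), with 24 of 31 genes negative and 0 passing over all probe sets or adjusted over the list alone. They included SLC1A5, a glutamine transporter (-1.60), PHGDH, which starts serine synthesis (-1.27), and AARS1 (-1.19). Interferon-stimulated genes had a mean difference of 0.17 (adjusted p = 0.538). The other 26 lists had adjusted p of 0.1001 and above.

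The siCTL comparison cannot be told apart from the array split, which leaves the mock array alone on its side among the controls. TKT was at 5161 on siDJ1 array 1 and 705.5 on siDJ1 array 2, and CCL20 at 40.8 and 368.0. Of 4170 probe sets with both siCTL arrays beyond siMOCK by at least 1.5-fold, siDJ1 array 1 lay within 1.5-fold of siMOCK for 63.1% and beyond it in the siCTL direction for 34.0%, while siDJ1 array 2 lay beyond it for 76.9%. All 4 siRNA-treated arrays were beyond siMOCK for 1301 probe sets, 767 higher and 534 lower. Leaving out either siDJ1 array gave 4356 or 4362 called probe sets, with the spread resting on the 2 siCTL arrays.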

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

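The array split as a block, alone or with quantile normalisation, and the separate changes inside the split were chosen after the data were examined; the other settings were planned. Over 16 settings with camera at the preset correlation the G2/M and replication lists passed and kept their sign in all 16, chaperones and inflammatory genes passed in 15, interferon-stimulated genes in 14 and complexes II to V in 4; with an estimated correlation none passed (adjusted p = 0.980). For 68 named probe sets, 956 values under alternatives were computed; 758 kept direction and side of the threshold, 192 passed it newly and 6 turned sign; the main fit had no call to lose. MAS5 signals near background limit what dim probe sets can show.

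For siDJ1 against siCTL the 0 probe sets became 4 with the 60th percentile filter (TMED2, TOMM20, SUB1 and 1 unnamed here, all lower; named after their values were seen; fewer probe sets tested), 755 by a rule of 1.5-fold beyond both siCTL arrays, 268 with the array split as a block and 153 with that and quantile normalisation. With the replicate number as a block it was 198 (81 higher, 117 lower) and PARK7 passed at -1.89 (limma adjusted p = 0.0118). The labels do not say whether the numbers pair the arrays. Across probe sets the deviations of same-numbered siCTL and siDJ1 arrays correlated at 0.00796. This cannot decide it, because the 2 siDJ1 arrays lie on opposite sides of the split, which could hide a pairing. With the replicate number as a block complexes II to V did not pass and no other list call changed. PARK7 passed at -1.74 with the array split as a block and at -1.75 with quantile normalisation added, and was -1.60 in siDJ1 array 2 alone against siCTL; NRF2 targets were -0.19 in siDJ1 array 1 against siMOCK. Over all its tested alternatives PARK7 had an adjusted p from 0.0038 to 0.658.

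With an estimated correlation or with fry, 0 lists passed for siDJ1 against siCTL and 0 for siCTL against siMOCK; with the 60th percentile filter the latter also had 0. Probe sets changed in siCTL against siMOCK numbered 1 with quantile normalisation (HUWE1, on 1 of 2 probe sets) and 4 with the 60th percentile filter (HUWE1, LMAN1, CXCL8, CD46). Probe sets separating siDJ1 from all controls numbered 376 with no filter (more probe sets) and 55 with a 2-fold gap. KEAP1 turned to -0.0679 with the array split as a block and -0.0658 with quantile normalisation added. GCLC on 202923_s_at turned to 0.0168 with quantile normalisation and ranged from -0.19 to 0.12 when 1 array was left out, being positive without siCTL replicate 1 (0.05) or siDJ1 replicate 2; on 202922_at the range was -0.122 to 0.0721, the positive value without siDJ1 replicate 1. Where no cause is given, the cause was not tested.

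Leaving out 1 array in turn gave 0 to 3766 probe sets for siDJ1 against siCTL, 9 to 3969 for siDJ1 against siMOCK, 0 to 4362 for siCTL against siMOCK, 1 to 4 lists for siCTL against siMOCK, 314 to 891 separating probe sets and PARK7 from -2.18 to -1.60. The highest counts came without a siDJ1 array. In the tests, 1 residual degree of freedom between the 2 close siCTL arrays then sets the spread, and the lone siDJ1 array is assumed to vary like them. The array split also enters these counts. Comparisons across the split called far more probe sets than comparisons on the same side of it. The count of separating probe sets uses no spread. Slide and scan date as a block were not run.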

Other observations

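The tests of the array split in the cell cycle lists, of matched random lists, of siRNA presence and of exchanged arrays were chosen after the results were seen, as were the genes named in the next paragraph, which are calls of the model with the array split as a block that no rule had named.

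Beyond the named genes, that model's calls with the smallest adjusted p were mostly lower in siDJ1. TOMM20, the receptor of the mitochondrial protein import pore, fell by 2.20 log2 units on 200662_s_at, from 2588 on siMOCK and 3327 ± 151.7 in siCTL to 627.9 ± 53.6 in siDJ1 (SD, n = 2 each), while its other kept probe set, 212773_s_at, differed by 0.17. The sorting receptor SORL1 fell by 1.91, the small GTPase RRAS2 by 1.85, EPAS1, a hypoxia-inducible transcription factor, by 1.49, and the zinc transporter SLC39A6 by 1.52. Other kept probe sets did not pass, at -0.41 for SORL1, 0.21 and 0.26 for RRAS2 and -0.87 for SLC39A6. For the called probe sets of TOMM20 and these 4 genes limma adjusted p-values lay between 0.00273 and 0.00826. GREM1, a secreted antagonist of bone morphogenetic proteins, rose by 1.84, with its other probe set at 1.03, and the small GTPase RHOB by 1.40. Among list members, the fatty acid desaturase SCD fell by 2.11 on 1 probe set, but its other 3 kept probe sets were at 1.40, 0.36 and -0.08. The chemokine CXCL3 fell by 1.35, the NF-kB inhibitor NFKBIA by 1.06 and the matrix protein TGFBI by 0.79, and INSIG1, a regulator of sterol synthesis, rose by 1.06, with its other 2 probe sets at 0.29 and 0.51. The chaperone CALR rose by 1.44 on 200935_at, while its 2 brighter probe sets were at -0.05 and 0.02.

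A model of the split itself called 3500 probe sets, 1485 higher and 2015 lower on the arrays with high ribosomal RNA. Cytosolic ribosomal proteins, proteasome subunits, complex I and complexes II to V were higher on those arrays, by 0.39, 0.45, 0.34 and 0.29 log2 units on average, and ATF4 and amino acid response genes lower by a mean of -0.53. These lists passed camera with the preset correlation, and none passed with an estimated one (smallest adjusted p = 0.894).

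The split of siMOCK and siDJ1 array 1 from the other arrays was weighed further. The presence of siRNA as the whole cause is argued against, since siDJ1 array 1 received siRNA and yet 1309 probe sets set it apart together with siMOCK by 1.5-fold, against at most 369 for any other choice of 2 arrays. A part played by siRNA stays open, because siMOCK alone was set apart from the 4 siRNA-treated arrays by 1301 probe sets. An exchange of a siDJ1 array with a control is argued against by PARK7, which lay at least 1.347 log2 units lower on both siDJ1 arrays than on any control. A hypothesis is that a property shared by neighbouring genes, such as regional base composition acting during labelling, contributed: the split effect of genes adjacent on the chromosome correlated at r = 0.2453 over 8183 pairs, above all 1000 shuffles of the gene order (highest 0.0351), and still at 0.128 for genes 20 places apart, while the siDJ1 effect of adjacent genes correlated at -0.00106. Base composition itself was not measured, and a shared culture or preparation of the 2 arrays, with a biological difference between cultures, stays open and untested.

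The lower cell cycle and replication lists were weighed against 2 explanations. The array split as the whole cause is argued against, since the 4 mean changes of the 2 lists inside the split were all negative and the one nearest to 0 was -0.2848. A general effect of expression level is argued against because 0% of 10000 random lists matched on signal had a mean as low as the G2/M list. The replication, interferon and inflammatory lists also gave 0%, so this does not set the G2/M list apart. Random lists also do not carry the correlation between genes of a list. Slower proliferation after DJ-1 loss is a hypothesis the values of the cell cycle and replication lists may fit. No list passed with an estimated correlation, but with 2 residual degrees of freedom that test has little power and leaves the question open. Counts of cells or a measure of DNA content in siDJ1 and siCTL cultures would decide on slower proliferation, and neither is in the data. Effects of the oligonucleotides on other transcripts were not tested, because their sequences are not given in the sources used here.

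The 268 probe sets called with the array split as a block were set against other choices of 1 array from the low pair and 1 from the high trio as the treated arrays. Of the 6 choices only 1, the labelled one, gave as many, and the highest of the others gave 0; 6 choices are too few for a share under 0.05. Over all 13329 probe sets, the change of siDJ1 array 1 from siMOCK and that of siDJ1 array 2 from siCTL, which share no array, had the same sign for 58.9% and correlated at r = 0.307 and Spearman's rho = 0.288 across probe sets, which are not independent replicates. The change from siMOCK also holds any effect of receiving siRNA.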
